A study of Sus scrofa with 8 samples.

How the data were processed

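Whole blood of 8 female Clawn miniature pigs, 4 on a control diet and 4 on a diet with shochu distilled water (SDW), was profiled on Agilent 1-colour arrays with 1 array per animal. Per the labels' protocols, blood was kept in PAXgene tubes, RNA was isolated with the matching kit, and Cy3-labelled cRNA was made from 0.5 µg of RNA by linear amplification.

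The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction, version 10.1.1.1 per the file headers and version 9.5.3.1 per the submitters' processing notes. Per the file headers, the processed signal is the spot intensity after background subtraction and detrending within the array, with a substitute value near background, and there is no normalization between arrays. The headers also give flags for spots well above background, saturated spots and outlier spots. The authors' value table holds intensities of the same arrays that are not centred and share nearly the same quantiles in all columns (75th percentiles from 52.4 to 52.9, medians from 5.02 to 5.14); the method behind it is not given in the sources used here. Set against the scanner files, 7 of its 8 columns matched the file of another replicate of the same diet and not the replicate of their label (Spearman correlation across probes, rounded, 1.00 with the match and from 0.856 to 0.906 with the labelled replicate). Diet was the same under both readings, so the comparison of the diets does not depend on it, but a replicate number does. All replicate names here follow the scanner files.

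From the processed signals, control spots and outlier spots were left out, spots of 1 probe were averaged (50 probes had more than 1 spot), and log2 values were taken minus the 75th percentile of the array. The 75th percentile of the signal was 51.6 ± 7.53 (SD, n = 4) in controls and 53.8 ± 16.5 (SD, n = 4) in SDW animals, and between 35.2% and 43.5% of the 43603 probes were well above background on an array. A probe was kept when well above background on at least 4 of the 8 arrays, whatever the diet, which left 17352 probes; 13658 were so on all 8. Of all probes, 3337 had a gene symbol: 2002 through a RefSeq accession, 684 through the symbol in the file that the pig gene table also holds, 132 through a synonym, 120 through a gene number, 286 through the probe description and 113 through a symbol in the file that the table lacks. The other 40266 are unnamed here. Some names are old, and ATP5J2 and ATP5MF, symbols of the same gene, both stand in the respiratory chain list. No genome was used, so positions of probes are not given.

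The diets were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the kept probes, threshold an adjusted p of 0.05), with no covariate, since the labels name no test. A gene was read from its kept probe of highest mean level, and other probes of opposite sign are given beside the gene. The genes named were set by a rule: 12 higher and 12 lower genes past the threshold by size or, where fewer pass, those with the smallest unadjusted p and an absolute log2 difference of at least 0.5; up to 4 members of smallest p in each of the 8 lists with the smallest fry p; and 9 reference genes. Of the genes set by this rule, 1 is not reported here. The OAS1 probes and the unnamed probe of the closing section fall outside it and were chosen after their values were seen. Of 40 gene lists, 30 had at least 5 measured genes and were tested with fry; the 10 too small were B cell (3 genes), circadian clock (1), dendritic cell (2), erythroid (3), gamma-delta T cell (1), hepatocyte (4), mitochondrially encoded (2), NK and cytotoxic cell (3), plasma cell (0) and unfolded protein response (2). A list score per animal, the mean over list genes of the level relative to each gene's mean, was compared by an exact permutation test over 70 assignments, two-sided. fry tests whether the genes of a list move one way and does not set them against other genes. The design, the rule, the lists and most alternatives were fixed before the data were examined.

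Slide and scan day were taken from the files as batches; each of the 3 slides held both diets, so slide was fitted as a fixed and as a random block (consensus correlation within slide 0.346). The replicate numbers of the labels were checked for pairing by the correlation of deviations from the diet means. They gave -0.17, 0.11, 0.33 and -0.38. Only the pair at 0.33 shares a slide, and those at -0.17 and -0.38 each set a slide 3 array against another slide. Slide and pairing therefore cannot be told apart, and whether the labels' numbers pair the animals stays open. The numbers of the authors' value table gave 0.28, 0.25, 0.51 and 0.64, and 3 of those 4 pairs share a slide. Other alternatives were normexp background correction (offset 50), quantile and median normalization, other filters on dim probes, the authors' value table, array weights, a variance trend, each array left out, camera in place of fry, the mean of all probes per gene and, added after seeing the data, leaving out both arrays of slide 3, a percentile over detected probes, removal of each array's trend with the GC content of the probe (lowess span 0.5), names without those from descriptions, and probe sets of immunoglobulin and T cell receptor chains.

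The fitting steps were tested on simulated data for the same comparison, over 17343 probes with a value on every array: of 100 probes changed by 1 and 100 changed by 2 on the log2 scale, 9 and 66 were called in the right direction, with median fitted changes of 1.02 and 2.01, and 6 unchanged probes were called. Of 4 lists of probes shifted by 1, fry called 4, and it called 0 of 20 unchanged lists. The simulated probes were drawn independently, without a slide effect, and all 10 probes of a shifted list moved alike. In the real lists, the correlation between genes estimated by camera ran from -0.03 to 0.73. The simulation therefore says little about how often limma calls or misses real probes, or fry the real lists. Of the 28 array pairs, 27 had 0 probes with exactly equal signals and 1 had 1 (control 3 and SDW 2). Figures were drawn with matplotlib. Blood cell counts were not used here, so differences in RNA level can come from cell composition or from regulation within cells.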

Results

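Whole blood gene expression was measured in 8 female Clawn miniature pigs, a small breed, aged 8 to 9 months. Of these, 4 received the standard dry feed (control) and 4 received the dry feed mixed with water and shochu distilled water (SDW) in equal parts by weight; shochu is a Japanese distilled spirit, and the labels say no more of the liquid. Each animal gave 1 array, a glass slide area carrying DNA probes of 60 bases for pig transcripts, read in 1 colour (Cy3). The design text places the sampling at 12 weeks of feeding, whereas the sample descriptions give 14, 15, 16 and 17 weeks for replicates 1 to 4 of each diet, so the exact duration is open. Of 43603 probes, 17352 were well above background on at least 4 of the 8 arrays and were tested, and 1860 of these carried a gene symbol, for 1241 genes. Levels are log2 spot intensities relative to the 75th percentile of the same array, and the number of arrays limits the precision.

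The arrays of both diets were alike in the measures of quality that were tested. The share of probes well above background was 38.6% ± 2.95 (SD, n = 4) in controls and 40.5% ± 2.69 (SD, n = 4) in SDW animals (p = 0.400, exact permutation test, two-sided). The 20 brightest probes took 12.6% of the total signal in controls and 12.5% in SDW animals (p = 0.943, exact permutation test, two-sided), and 0 probes were saturated. With 70 assignments of 4 of 8 animals, the smallest p such a test can give is 0.0286. The 8 arrays lay on 3 slides, each holding both diets: control 3, SDW 2 and SDW 3 on slide 1; control 2, control 4 and SDW 1 on slide 2; control 1 and SDW 4 on slide 3, which was scanned on a second day.

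The largest spread in the blood profiles lay between slides and not between diets. Component 1 of a principal component analysis held 42.8% of the variance and set control 1 (score -88.7) and SDW 4 (score -72.5), the arrays of slide 3, apart from the other 6 arrays, whose scores were positive and reached 38.1. Component 2 held 21.4% and had SDW 1 at one end (score -68.9). Diet accounted for 8.94% of the variance over all kept probes and slide for 54.0%. An even share for 1 of the 7 independent directions among 8 arrays is 14.3%. Slide takes more than 1 of these directions, so its even share is larger. Over the 35 splits of the animals into equal groups the median share was 11.2%, and 27 splits held at least as much as the diets. The median SD of a probe was 0.41 on the log2 scale among controls and 0.42 among SDW animals, against a median absolute difference between the diets of 0.17.

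**Figure D1:**
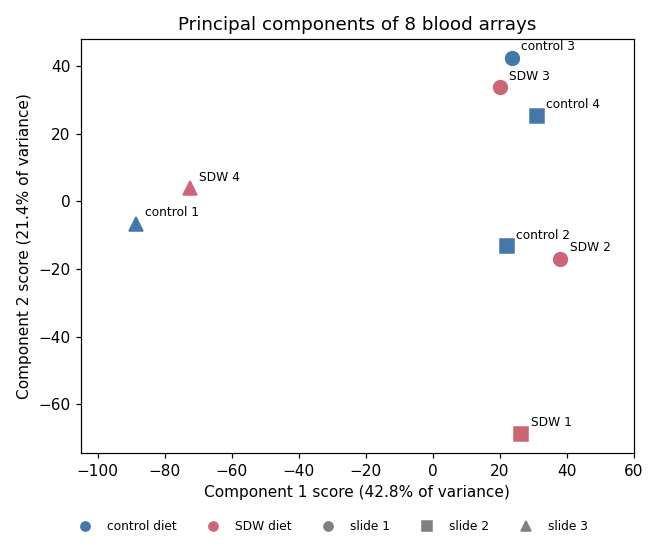
Scores of the 8 arrays on components 1 and 2 of the kept probes, in arbitrary units with the share of variance on each axis; colour gives the diet and marker shape the slide. Control 1 and SDW 4, both on slide 3, sit at -88.7 and -72.5 on component 1, away from the other 6 arrays.

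The comparison of SDW with control addressed how the feed acts on blood mRNA levels. No probe passed the threshold: the limma test called 0 of 17352 probes at an adjusted p under 0.05, the smallest adjusted p being 1.00 after rounding. At an unadjusted p under 0.05 there were 251 probes, where evenly spread p-values would give 868. Counted after the data were seen, 20 splits of the animals into equal groups part the slide 3 arrays, as the diets do. Their median was 269.5 such probes, and 13 of them, the diets included, gave at least 251. The figure of 868 is therefore no yardstick for this design. Of the 251 probes of the diets, 161 were higher and 90 lower in SDW animals, and 65 differed by at least 1 on the log2 scale. The count of 65 was 4 with normexp background correction, whose offset compresses dim probes, and 271 with slide as a fixed block. Every SDW animal lay above every control animal for 104 probes and below for 67, which is 0.985% of the probes. The mean over all assignments of the animals is 2.86%. It includes those that keep the slide 3 arrays together, so it is no yardstick for the diets either. With slide as a block in limma, 0 probes passed (smallest adjusted p 0.319) and the count at unadjusted p under 0.05 was 1143, with 589 higher and 554 lower. The count at unadjusted p under 0.05 came to 420 without control 1, 441 without SDW 3 and 517 without SDW 4, with 0 adjusted calls each time. With the pairs of numbers that the authors' value table gives as a block, 0 probes passed and 904 had an unadjusted p under 0.05. In data simulated with the spread of these animals, limma called 9 of 100 probes changed by 1 and 66 of 100 changed by 2 on the log2 scale. The simulated probes were independent, had no slide effect and took the spread of the fit without a block. The simulation therefore sets no detection limit for the real arrays or for the fits with a slide block.

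Because none passed, the 12 higher and 12 lower named genes with the smallest unadjusted p are given as values only, and a choice by small p favours overstated sizes. Among genes of white blood cells and their precursors, LGALS1, a galactoside-binding lectin of immune cells, stood at 6.01 ± 0.13 (SD, n = 4) in controls and 6.96 ± 0.40 (SD, n = 4) in SDW animals, a log2 difference of 0.95 with a standard error of 0.25 (limma, unadjusted p = 0.00353). CCR2, the receptor of inflammatory monocytes for the chemokine CCL2, was at 1.80 ± 0.23 in controls and 2.69 ± 0.32 in SDW animals, a difference of 0.88 with a standard error of 0.24. CD34, a marker of blood progenitors, differed by 0.96. ALOX15, a lipoxygenase of eosinophils, differed by 0.82, CCL24, a chemokine that attracts eosinophils, by 0.89, and PF4, a chemokine stored in platelets, by 0.63. The remaining higher genes were COX8H, a cytochrome c oxidase subunit (0.95), TMEM57 (0.72), SCD, a fatty acid desaturase (0.64), the membrane carrier protein SCAMP1 (0.63), PIR (0.63) and MMD (0.58). CD34 was well above background in 2 of 4 controls and 3 of 4 SDW animals and SCAMP1 in 3 and 4, so their differences include values near background. A second probe of SCAMP1 gave 0.13. ALOX15 came to 0.54 without SDW 1, and SCD to 0.42 without control 1 and 0.33 without slide 3.

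Among the lower genes, LY75, an endocytic receptor of dendritic cells, was at -0.27 ± 0.22 (SD, n = 4) in controls and -1.44 ± 0.39 (SD, n = 4) in SDW animals, a log2 difference of -1.16 with a standard error of 0.26 (limma, unadjusted p = 0.00112). PTH1R, the parathyroid hormone receptor, differed by -1.06 with a standard error of 0.29, and TCTEX1D4, of the dynein light chain family, by -1.38 with a standard error of 0.48. CFLAR, an inhibitor of death receptor signalling, differed by -0.66, and CD46, which protects cells from complement, by -0.68. GNLY, the cytolytic protein granulysin, differed by -0.71, and SLA-DQB1, an MHC class II chain, by -1.06. TGFA (-0.64), CGA (-0.84), GPM6A (-0.81), PCGF2 (-0.51) and B4GALT4 (-0.71) completed the set. LY75 was well above background in 4 of 4 controls and 3 of 4 SDW animals, GPM6A in 3 and 3 and B4GALT4 in 3 and 2, so their differences include values near background. GPM6A came to -0.53 without SDW 2.

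For 9 of these 24 genes the animals of the diets did not overlap: LGALS1, CCR2, COX8H, SCAMP1 and PIR above, and LY75, PTH1R, CFLAR and CD46 below. The 24 were chosen by small p on these same arrays, which favours both no overlap and a shared sign across slides. Neither is therefore independent support for a difference. Over all kept probes, 0.985% did not overlap, where the mean over all assignments of the animals is 2.86%. The share with a shared sign was not counted. Within slides 1, 2 and 3 the SDW minus control difference of LGALS1 was 1.12, 0.90 and 0.65, that of CCR2 0.89, 0.90 and 0.68, that of LY75 -0.90, -0.82 and -1.88, and that of PTH1R -1.10, -1.54 and -0.79. In all, 19 of the 24 genes kept their sign on all 3 slides. With slide as a block, LGALS1 differed by 0.91, CCR2 by 0.84, LY75 by -1.14 and PTH1R by -1.17, and the smallest adjusted p of any named gene was 0.732 in limma. The exceptions were SLA-DQB1, at -2.29, -1.12 and 0.31 within the slides, CCL24, at 2.11, 0.72 and -0.25, and ALOX15, SCD and TGFA, each close to 0 with the opposite sign on 1 slide (-0.01, -0.01 and 0.05).

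**Figure D2:**
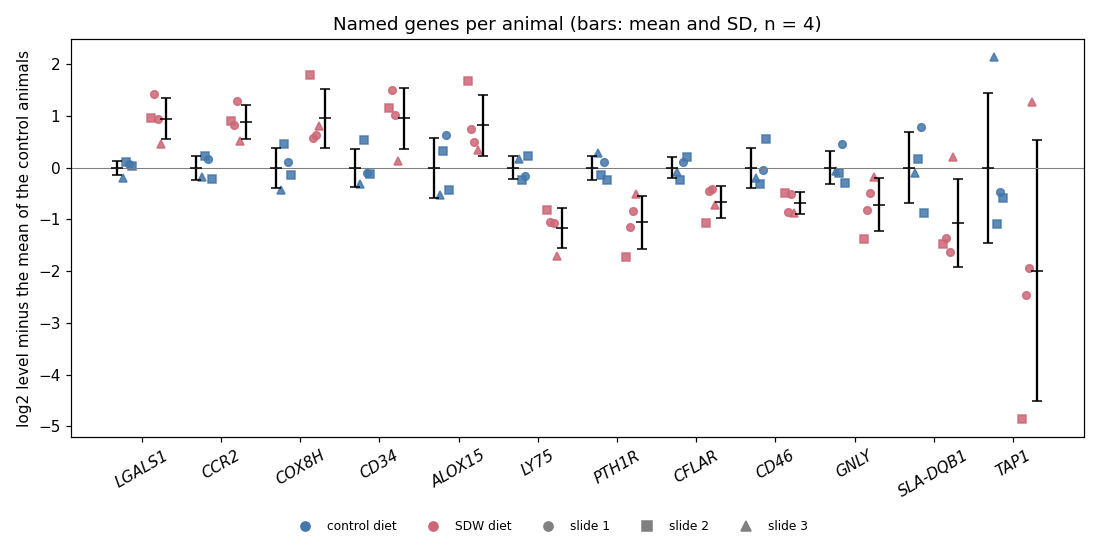
Log2 level of 12 named genes in each animal, relative to the mean of the 4 controls; colour gives the diet, marker shape the slide, and bars the mean and SD of each diet. The SDW animals lie above every control for LGALS1, CCR2 and COX8H and below every control for LY75, PTH1R, CFLAR and CD46, while those of TAP1 span more than the distance between the diets.

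None of the reference genes passed the threshold. ACTB, the cytoskeletal beta actin, differed by 0.17 with a standard error of 0.22 (limma, unadjusted p = 0.463), though its 4 probes ranged from -0.49 to 0.27. CD3E, a T cell receptor subunit, differed by -0.31 with a standard error of 0.44, and with 1 array left out its difference went from 0.08 (without control 1) to -0.58 (SDW 4) and that of ACTB from 0.07 (control 1) to 0.24 (control 2). CD14, the monocyte co-receptor for endotoxin, differed by -0.73 with a standard error of 0.49 (limma, unadjusted p = 0.170), and its second probe by -1.19. With slide as a fixed block it differed by -0.90 with a standard error of 0.28 (unadjusted p = 0.0110; adjusted p = 0.732), and within slides 1, 2 and 3 by -1.23, -1.18 and -0.10. No kept probe was named for HBB, HBA, GAPDH, B2M, CD79A or S100A8.

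Gene groups of blood cells and metabolism were compared next: 0 of 30 lists passed an adjusted p of 0.05 in fry, limma's rotation test of a common direction, every adjusted p being 0.976, and 1 list had an unadjusted p under 0.05. By camera with a preset correlation 2 lists passed, neutrophil and eosinophil markers, with an adjusted p of 0.0300 each; both calls were lost with an estimated correlation, at an adjusted p of 0.533. The exact permutation test of the score of each list per animal gave 0 lists at p under 0.05; alcohol metabolism without control 3 and glycolysis without SDW 3 reached p = 0.0286 in that exact test. With slide as a random block in limma, 3 scores came under 0.05, those of neutrophil, eosinophil and MHC class I genes (unadjusted p = 0.0177, 0.0308 and 0.0347), where the exact permutation test within slides gave p = 0.0556, 0.111 and 0.0556 and cannot go below 0.0556. In fry, 1 list passed without a filter on dim probes (cytotoxic cell genes, adjusted p = 0.0262). Without both arrays of slide 3 and with the slide block, 1 passed (fatty acid oxidation, adjusted p = 0.0190). Without slide 3 but with no block, that call was lost (fry, adjusted p = 0.983). No member of any list passed, either over all probes or adjusted over the list alone (0 members of 30 lists).

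Granulocyte groups came next. All 10 measured neutrophil markers were lower in SDW animals, with a median log2 difference of -0.41 (fry, unadjusted p = 0.0497; adjusted p = 0.976). Among them were TREM1, an activating receptor of myeloid cells (-0.87), LTF, the granule protein lactoferrin (-0.76), NCF1, an NADPH oxidase subunit (-0.76), and ALOX5AP, which takes part in leukotriene synthesis (-0.42). Control 1 stood apart from the other controls for TREM1 (4.68) and NCF1 (4.00). SDW 4, on the same slide, was the highest SDW animal for both (3.87 and 3.54). TREM1 ranged, with 1 array left out, from -0.51 (without SDW 2) to -1.25 (SDW 4), LTF from -0.37 (without control 1) to -1.24 (control 2), NCF1 from -0.23 (without control 1) to -1.38 (SDW 4) and ALOX5AP from -0.33 (without SDW 3) to -0.57 (SDW 1). The score of the list was 0.21 ± 0.33 (SD, n = 4) in controls and -0.21 ± 0.24 in SDW animals (p = 0.0857, exact permutation test), and the difference within slides 1, 2 and 3 was -0.86, -0.27 and -0.27. The block for slide gave a median of -0.45 (fry, unadjusted p = 0.0478; adjusted p = 0.474). Of 6 eosinophil, basophil and mast cell markers, 5 were higher, with a median of 0.49 (fry, unadjusted p = 0.248; with the slide block, 0.0790). The median came to 0.27 without control 1 and to 0.17 with normexp and quantile normalization. MS4A2, a chain of the high-affinity IgE receptor, differed by 0.97, CCR3, the eotaxin receptor, by 0.53, and HDC, which makes histamine, by 0.45. MS4A2 and HDC were each well above background in 3 controls and 4 SDW animals, so their differences include a value near background. MS4A2 ranged, with 1 array left out, from 0.45 (without control 1) to 1.26 (control 2), CCR3 from 0.26 (without control 1) to 0.82 (SDW 4) and HDC from -0.02 (without control 1) to 0.70 (control 4). The score was highest in SDW 1 (0.65) and lowest in control 1 (-0.87). The score difference of 0.43 between the diets came to 0.21 without control 1 and 0.28 without SDW 1. The score differences within slides were -0.03, 0.68 and 0.97.

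In immune sensing and antigen presentation, 8 of 9 genes of the MHC class I pathway were lower, with a median of -0.45 (fry, unadjusted p = 0.426), and the slide block gave -0.55 (unadjusted p = 0.0107; adjusted p = 0.160). The median came to -0.08 without control 1 and -0.06 without SDW 1. TAP1, a peptide transporter, differed by -1.99 with a standard error of 1.15, being well above background in 4 controls and 2 SDW animals. SLA-7, a class I gene, differed by -0.62 and the immunoproteasome subunit PSMB8 by -0.50, while PSMB10 was at 0.23. TAP1 ranged, with 1 array left out, from -1.04 (without SDW 1) to -3.08 (SDW 4), SLA-7 from -0.08 (without control 1) to -1.14 (SDW 4), PSMB8 from -0.30 (without control 1) to -0.61 (control 4) and PSMB10 from 0.03 (without control 4) to 0.35 (SDW 4). The class I score was highest in both animals of slide 3, at 0.94 in control 1 and 0.61 in SDW 4, and within slides 1, 2 and 3 the diets differed by -0.60, -1.04 and -0.32. Of 16 Toll-like receptor and innate sensing genes 11 were lower, with a median of -0.22 (fry, unadjusted p = 0.313; with the slide block, 0.270), and without control 3 the median turned to 0.02. Among them were IRF3 (-1.07, with control 1 apart at 1.08 and SDW 4 the highest SDW animal at -0.08), CD14 (-0.73), TBK1 (-0.62) and TLR2 (-0.36). IRF3 was well above background in 3 controls and 1 SDW animal, and TBK1 in 3 and 2. IRF3 ranged, with 1 array left out, from -0.28 (without control 1) to -1.83 (SDW 4), CD14 from -0.41 (without SDW 1) to -1.16 (SDW 4), TBK1 from -0.27 (without SDW 3) to -0.90 (SDW 2) and TLR2 from -0.29 (without SDW 3) to -0.43 (SDW 4). The score differences within slides were -0.41, -0.08 and -0.19.

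Metabolic groups followed, and none passed the threshold. Of 9 glycolysis genes 7 were higher, with a median of 0.26 (fry, unadjusted p = 0.137; with the slide block, 0.214). The median came to 0.06 with normexp and quantile normalization and 0.03 with normexp and the 75th percentile. Among the higher were the glucose transporter SLC2A1 (0.37), HIF1A (0.35), PFKFB4 (0.31, well above background in 1 control and 4 SDW animals) and PGAM1 (0.26). SLC2A1 ranged, with 1 array left out, from 0.15 (without SDW 4) to 0.54 (SDW 2), HIF1A from 0.11 (without control 1) to 0.65 (control 4), PFKFB4 from 0.09 (without control 3) to 0.52 (control 1) and PGAM1 from 0.18 (without SDW 1) to 0.40 (SDW 3). Of 7 sterol synthesis genes 5 were higher, with a median of 0.36 (fry, unadjusted p = 0.162; with the block, 0.228), including SQLE (0.58) and MSMO1 (0.51), while INSIG1, which restrains sterol synthesis, was at -0.54 (its second probe at -0.15). The sterol median came to 0.20 with normexp and quantile normalization, 0.21 with normexp and the 75th percentile and 0.13 without slide 3. SQLE ranged, with 1 array left out, from 0.34 (without control 1) to 0.77 (control 3), MSMO1 from 0.39 (without control 1) to 0.65 (SDW 4) and INSIG1 from -0.26 (without SDW 1) to -0.90 (SDW 3). Of 18 genes of fatty acid oxidation and PPAR targets 14 were lower, with a median of -0.11 (fry, unadjusted p = 0.212), and the slide block gave -0.19 (unadjusted p = 0.0105; adjusted p = 0.160). ANGPTL4 (-1.13), PPARD (-0.72), PLIN2 (-0.41) and CPT1A (-0.36) were its named members. ANGPTL4 was well above background in 3 controls and 1 SDW animal and PPARD in 3 and 2. ANGPTL4 ranged, with 1 array left out, from -0.31 (without SDW 1) to -2.03 (SDW 4), PPARD from -0.44 (without SDW 4) to -1.15 (SDW 3), PLIN2 from -0.15 (without SDW 1) to -0.64 (SDW 3) and CPT1A from -0.23 (without control 3) to -0.52 (control 1). Of 5 genes of alcohol and aldehyde metabolism 4 were higher, with a median of 0.19 (fry, unadjusted p = 0.408; with the block, 0.561). These were led by AKR1A1 (0.44, its second probe at -0.22), the catalase gene CAT (0.34) and ALDH2 (0.19, its second probe at -0.34), with CES1 at -0.13. AKR1A1 ranged, with 1 array left out, from 0.30 (without control 1) to 0.61 (control 3), CAT from -0.03 (without control 1) to 0.63 (control 3), ALDH2 from 0.06 (without control 2) to 0.36 (control 3) and CES1 from 0.25 (without control 3) to -0.35 (SDW 3). Within slides 1, 2 and 3 the score differences were 0.14, 0.36 and 0.05 for glycolysis, -0.16, -0.09 and 0.38 for sterols, -0.39, -0.43 and -0.11 for fatty acid oxidation, and -0.27, 0.20 and 0.31 for alcohol metabolism.

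**Figure D3:**
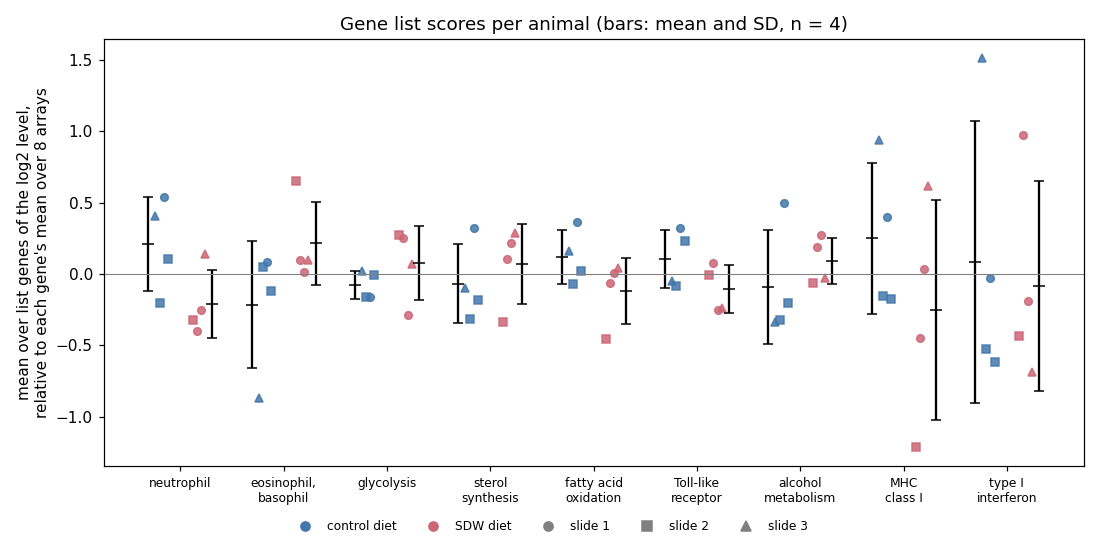
Score of 9 gene lists in each animal, the mean over list genes of the log2 level relative to each gene's mean over the 8 arrays; colour gives the diet, marker shape the slide, and bars the mean and SD of each diet. The neutrophil score is 0.21 in controls and -0.21 in SDW animals on average, with overlapping animals, and the type I interferon score reaches 1.51 in control 1 and 0.97 in SDW 2.

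The other 22 lists had unadjusted fry p between 0.467 and 0.976. For cell types, the median log2 difference was 0.01 for 18 monocyte markers, -0.10 for 12 T cell markers and 0.11 for 8 platelet markers. For defence, it was -0.45 for 6 antimicrobial peptides, -0.14 for 16 type I interferon genes, -0.07 for 13 genes induced by interferon gamma, -0.11 for 12 inflammatory genes, 0.16 for 10 complement genes, -0.06 for 10 T helper genes and 0.10 for 5 MHC class II genes. For metabolism and growth, it was -0.18 for 11 haem and iron genes, 0.07 for 18 respiratory chain genes, 0.04 for 19 antioxidant genes, -0.03 for 10 genes of fat synthesis, 0.04 for 6 genes of vitamin and amino acid response and -0.16 for 8 cell cycle genes. For the remaining groups, it was -0.05 for 40 ribosomal proteins, 0.02 for 5 proteasome subunits, 0.03 for 9 heat shock genes, -0.12 for 8 glucocorticoid-responsive genes, 0.05 for 9 immediate early genes and -0.03 for 12 apoptosis genes. Median and mean differed in sign for 7 lists (proteasome, immediate early, T helper, heat shock, MHC class II, vitamin and monocyte genes), and the direction of the fry test differed from the sign of the median for 5 (proteasome, heat shock, monocyte, complement and fat synthesis genes). The medians of 20 of these 22 lists turned sign under at least 1 other setting. Slide as a fixed block put 0 lists past the threshold in a common direction, and 1, the platelet markers, past it when changes in either direction count (fry mixed test, adjusted p = 0.0396). In it PF4 (0.81 with that block) was higher and THBS1 (-0.92) lower. The call was lost with slide as a random block (adjusted p = 0.808) and with no block (0.955). Over the settings other than the fixed block the adjusted p ran from 0.279 to 0.995.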

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

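All tests of explanations and all counts of other splits in this part were chosen after the results they bear on had been seen.

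Within each diet, a value was singled out when its gap to the nearest other animal took more than 0.829 of the range of the 4 animals, which chance gives for about 1 in 20 groups. Of 188 groups tested, 16 were singled out, where 9.4 are expected. Control 1 accounted for 6 of them and SDW 1 for 3.

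Among the log2 levels of genes, control 1 stood apart for TREM1 at 4.68, with the other controls from 3.24 to 3.35. It also did for NCF1 at 4.00, the others from 1.72 to 2.04, and for IRF3 at 1.08, the others from -2.27 to -1.93. For CD3E it was at 3.46, the others from 1.81 to 1.95. SDW 4, the other array of slide 3, was the highest SDW animal for TREM1 (3.87), NCF1 (3.54), IRF3 (-0.08) and CD3E (2.79). Slide and animal can therefore not be told apart for these genes. Control 3 stood apart for CES1 at -0.34 and control 4 for PSMB10 at 5.31, the others of that gene from 6.10 to 6.16. In SDW animals, SDW 1 stood apart for PF4 at 6.55, SDW 4 for SLA-DQB1 at 8.68, the others from 6.85 to 7.12, and SDW 3 for PCGF2 at 2.81, the others from 2.21 to 2.22. Among list scores, control 3 stood apart for alcohol metabolism at 0.50, control 1 for the cell cycle at -0.35, SDW 1 for eosinophil and basophil markers at 0.65, and SDW 2 for monocyte markers at 0.27. Among array measures, the spread of the negative control spots in SDW 1, at 5.96, lay below the other SDW arrays, from 6.56 to 6.68. Among controls it was 12.9 in control 1 and from 5.96 to 7.21 in the other 3, a gap just short of being singled out. On component 1, control 1 at -88.7 and SDW 4 at -72.5 stood apart within their diets.

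The pair on slide 3 is the largest structure in the data. The GC content of the probes is argued against as its whole cause. The 330 probes with over 45% GC lay 0.71 higher on slide 3 than on the other 6 arrays, and the 4849 up to 35% lay at -0.16. Removing the trend of each array with GC left the share of variance between slides at 53.9%, against 54.0% before. A shift confined to the 330 probes could barely move this share, so for those probes GC stays open. Transcript levels of these 2 animals and an effect on single probes cannot be told apart. Of the variance of the slide 3 difference, 46.1% lay between genes rather than between probes of a gene (bootstrap interval 37.7% to 53.0%, 405 genes). This spans the value of 50% set as the dividing line. The diet difference, which had no calls, gave 42.4% (34.4% to 51.2%), so the value is not particular to slide 3. Hybridisation or scanning of that slide also stays open. The deviations of 10 spike-in probes on its arrays correlated at 0.375, below the highest of the 21 pairs across slides, 0.735, and 10 probes are too few to decide. The brightest spike-in probe had a log2 signal of 18.18 in control 1 and 18.15 in SDW 4, against 17.58 to 17.80 on the other 6 arrays. Another was at 10.19 and 10.58, against 9.36 to 10.15. Both go with a technical difference of slide 3, but they were picked after the fact. The rest did not set both arrays apart from the other 6. The diets give no biological explanation for the pair, since both are on the slide, and no other was tested.

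Control 1 and SDW 2 had high levels of type I interferon genes, with list scores of 1.51 and 0.97 against -0.69 to -0.03 in the other 6 animals. A level shared by the arrays of a slide does not account for the pair. Control 1 exceeded SDW 4 on the same slide by a median of 2.07 and a mean of 2.20 over the 16 genes. The standard error of that mean, 0.31, was taken over genes that move together. It does not measure the spread between animals, since 1 array is set against 1 array. GC content is argued against, as the gap of 1.00 between SDW 2 and the next highest animal stayed at 0.99 with the trend removed. Diet does not account for a pair that holds both diets, and the list had a fry p of 0.789. The points on slide and diet follow from how the pair was picked out, so they are no separate tests. An antiviral response of individual animals is a candidate explanation that stays open and untested here.

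Of the 3 kept OAS1 probes, a pair were low in SDW 2 and SDW 4. The brighter of the pair was at -0.89 in SDW 2, still well above background, and not well above background in SDW 4, where the other animals ranged from 2.90 to 7.33. The dimmer was not well above background in either, where the others ranged from -1.75 to 1.07. With undetected values set to the lowest signal well above background on their array, or the probe's own if higher, the ranges are lower bounds. For the brighter probe, a lower level of the whole transcript is argued against only if the third probe reads OAS1, which was not checked. The brighter probe spanned at least 9.33 over the 8 animals and the third 1.16, with SDW 2 at 6.69 and SDW 4 at 7.10 on the third. Relative to its mean, the third probe was at 0.50 in control 1 and -0.18 in SDW 2, where the interferon list score was 1.51 and 0.97. For the brighter probe, a level shared by the arrays of a slide does not account for the pair of animals, which was picked for its low values. SDW 2 on slide 1 and SDW 4 on slide 3 lay at least 4.74 below the other arrays of their slides. For the dimmer probe, transcript level and slide both stay open. Its range was at least 3.96 and the difference within slides at least 1.95, which leaves room for either near the detection limit. A sequence or transcript variant under the 2 probes is a possible explanation that stays open, since 0 probes could be set against a genome.

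Other splits of the 8 animals do not exclude chance for the number of probes at unadjusted p under 0.05. At unadjusted p under 0.05, 28 of 35 splits gave at least the 251 probes of the diets, up to 2697 when control 1, control 2, SDW 1 and SDW 4 formed a group. The 15 splits that kept the arrays of slide 3 together gave from 627 to 2697 probes and the 20 that parted them from 112 to 1172, so splits that follow the slide call several times the real count, which points to a structure of the samples. With slide as a block, 11 of 35 splits gave at least the 1143 of the diets, up to 2809 for control 1, SDW 1, SDW 2 and SDW 4, and of the 18 that kept the real numbers per slide, 6 did. For the 0 adjusted calls and the 0 gene lists of the diets the splits decide nothing, since all 35 of 35 give at least 0; the highest of the others were 25 probes and 1 list without a block. With slide as a block, 11 splits had adjusted calls, up to 695 probes for control 1, SDW 1, SDW 2 and SDW 4.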

How the results depend on the processing

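The settings without slide 3 and the block with the numbers of the authors' value table were chosen after seeing the data. The limma count at an adjusted p under 0.05 was 0 in 24 of 26 alternative fits, and at 0.1 it was also 0; where it was not, the cause was not tested. Without both arrays of the second scan day it was 1, with and without slide as a fixed block. The count at unadjusted p under 0.05 with an absolute log2 difference of at least 1 was 65 with all arrays; it was 4 with either normexp setting, 20 for probes well above background on all 8 arrays, 105 with array weights, 134 with the numbers of the authors' value table as a block, 141 with slide as a random and 271 as a fixed block, 415 without a filter, 202 without the second scan day and 711 with the slide block added, and 63 to 205 with 1 array left out. At unadjusted p under 0.05 the count was 251; it was 162 with normexp and the 75th percentile, 165 for probes well above background on all 8 arrays, 399 with array weights, 632 with slide as a random block, 1143 with slide as a fixed block, 542 without both arrays of the second scan day and 1439 with the slide block added. Without a filter it was 823 of 43603 probes, 269 higher and 554 lower, against 161 and 90, and the median of all probes was -0.15. It ranged from 179 to 517 with 1 array left out, and was 420 without control 1, 441 without SDW 3 and 517 without SDW 4. The adjusted count was 0 in each of these 8 fits.

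The replicate numbers of the labels as a block gave 239 probes (114 higher, 125 lower) and 0 adjusted, and 1 of 4 controls correlated best with the SDW animal of its number. The numbers of the authors' value table as a replicate block gave 904, and 3 of 4 controls did. No call changed under either block.

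Lists past the fry threshold in a common direction were 0, except 1 without a filter (cytotoxic cell genes), 1 without the second scan day and with the slide block (fatty acid oxidation, adjusted p = 0.0190; over all alternatives of that list, unadjusted p from 0.000632 to 0.522), and 2 by camera with a preset correlation. Counting changes in either direction it was 0, except 1 with slide as a fixed block (platelet markers). With 1 array left out the number was 0 to 0 in both tests. The median of Toll-like receptor and sensing genes ranged from -0.32 to 0.017 with 1 array left out, turning sign without control 3; those of the other 7 lists with the smallest p kept their sign. Lists with a score p under 0.05 were 0, and 1 without a filter, 3 with slide as a random block (neutrophil, eosinophil and MHC class I genes, by limma), and 0 to 1 with 1 array left out: alcohol metabolism without control 3 and glycolysis without SDW 3 (exact permutation p = 0.0286 each, the smallest possible). Score tests within slides or within pairs could not go below 0.0556 and 0.125, nor could those without slide 3 pass the threshold, and these were not counted. Array quality measures gave 0 of 4 differences, with 0 to 0 on leaving out 1 array. Saturated probes, 1 of the 4 measures, were 0 on every array and so could show no difference.

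Diet held from 7.89% to 9.00% of the variance under 3 alternatives. The median SD came to 0.21 in controls and 0.22 in SDW animals with normexp and quantile normalization, whose offset compresses dim probes; 27 of the 57 named genes, 13 of them among the 24 chosen by p, then had under 50% of their log2 difference. Without control 1 this held for 12 of the 33 named genes of lists and reference genes and without SDW 1 for 7. Of 1466 values of the 57 named genes under 26 alternatives, 6 turned sign and 0 passed the threshold: CES1 gave 0.25 without control 3 and 0.083 without SDW 1, HDC, CAT and CD3E turned without control 1, and CAT gave -0.17 without the second scan day and with the slide block. With 1 array left out, the log2 fold change ranged from -0.024 to 0.70 for HDC, from -0.030 to 0.63 for CAT, from -0.35 to 0.25 for CES1 and from -0.58 to 0.082 for CD3E. Between 35.2% and 43.5% of probes were well above background on an array, so dim probes have levels that rest on few arrays.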

Other observations

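The tests of receptor probes, of probes of the same gene and of the arrays of the first scan day were chosen after the values were seen; the setting without a filter was planned.

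Cytotoxic lymphocyte genes had too few kept probes to be tested in the report. Without a filter on dim probes, all 5 measured members were lower in SDW animals, with a median log2 difference of -0.43 (fry, adjusted p = 0.0262 over 33 lists). Every SDW animal had a lower score than every control (difference -0.44, exact permutation p = 0.0286, the smallest possible). The median of all probes was -0.15 in this setting, and neither test sets the list against other probes. A shift shared by all probes can therefore add to both results. GNLY (-0.71), KLRK1 (-0.57) and CCL5 (-0.17) were well above background on 8 arrays, PRF1 (-0.43) on 2 and FASLG (-0.30) on 0, so the call includes genes at the noise level, and no member passed alone.

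Interferon-stimulated genes differed far more between animals than between diets. Relative to its mean over the animals, MX1, an antiviral GTPase, was at 2.38 in control 1 and 1.22 in SDW 2, USP18 at 2.28 and 1.34, and RSAD2 at 1.94 and 2.32. OAS2, a synthetase of the same family as OAS1, was at 2.81 in control 1 but at -0.35 in SDW 2 and -1.79 in SDW 4.

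Immunoglobulin and T cell receptor chains are named only in probe descriptions. The 5 kept immunoglobulin probes had scores of 2.20 in control 1 and 2.03 in SDW 4, the arrays of slide 3, and from -1.63 to 0.11 in the other 6 animals; the diets differed by a median of -0.35 (fry, unadjusted p = 0.770; with the slide block, 0.0111). The 5 T cell receptor probes ranged from -0.29 to 0.32 (fry, unadjusted p = 0.858).

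Probes of the same gene disagreed. Of 405 genes with more than 1 kept probe, 29 had a probe that spanned at least 3 and another that spanned at most 1.5 on the log2 scale over the animals, values near background included. In ACTB, 3 probes spanned 0.60, 0.90 and 0.88, while the fourth, with 55% GC, was at 5.23 in control 1 and 5.10 in SDW 4 and from 0.71 to 2.38 elsewhere. SLC25A6 had the same picture, with slide 3 at 2.68 above the other arrays on a probe of 55% GC and at 0.05 on the other. A probe of CYB561 was at 3.15 in SDW 2 and from -3.59 to -1.29 in the other animals, while its second probe spanned 1.24.

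The probe that passed without the second scan day, A_72_P092736, has no gene name here. It was at 1.88 in control 1, 1.42 in SDW 1, 1.42 in SDW 2 and 1.47 in SDW 3, and not well above background in the other 4 animals (-3.92 to -2.54), so over all 8 arrays it was well above background in 3 of 4 SDW animals and 1 of 4 controls. Among the arrays of the first day it was well above background in 3 SDW animals and 0 controls, at least 13.6-fold higher, against the lowest signal well above background on each array or the probe's own, whichever was higher. Its adjusted p in limma there, 2.78e-05, rests on values near background in the controls.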
